A study of Arabidopsis thaliana with 6 samples.

How the data were processed

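Total RNA from Arabidopsis Col-0 rosette centres was labelled with biotin and measured on 6 ATH1 arrays, 1 for each combination of 3 light levels and 2 CO2 levels, per the labels. The deposited values are array signal intensity on a linear scale, made with MAS5 per the submitters' processing notes, version not given in the sources used here. The deposited intensity columns had the same 2% trimmed mean on every array, 100, so each array had been scaled to a common level before deposit. MAS5 gives 1 signal per probe set from perfect-match and mismatch probes, and low signals are noisy on a log scale. Detection calls were not used here. All labels carry replicate 1, and nothing says that the samples came from separate plantings, so p-values measure only the spread between these arrays.

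Signals were used as scaled, set to at least 0.1 and taken to log2. The 64 control probe sets were left out of the tests, and the 13648 probe sets in the top 60% of 22746 by mean log2 signal (mean signal at least 26.7) were tested. An additive model of CO2 and light, with light as a factor, was fitted with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with an intensity trend), and Python 3.11.15 drew the figures. This left 2 residual degrees of freedom, joined by a mean prior of 5.76. P-values were adjusted by the Benjamini-Hochberg method in each comparison, with a threshold of 0.05. A model with CO2, a light score and their product tested whether the CO2 difference changes along the light order.

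The probe annotation listed 14016 probe sets, 13513 with 1 gene and 503 with several, and 8730 are unnamed here. Of the single-gene probe sets, 13436 matched the gene table of assembly TAIR10.1 by gene number, which gave current symbols, and 7416 of the tested probe sets carried 1 gene. No coordinates are given. Before the data were examined, 25 gene lists with 403 members were fixed, as was the rule for named genes. For CO2 and for high minus low light the rule takes up to 12 rises and 12 falls with the largest change among those past the threshold and moving the same way in every pair, filled by smallest p among changes of at least 1 log2 unit. For other comparisons it takes 3 and 3, and from each list up to 4 members with the smallest p. Where a gene had several probe sets, gene-specific ones came first, then the brighter. Only 55 members were measured under the annotation, of which 48 were tested, and 3 whose symbol belongs to another locus in the gene table were left out. Lists with at least 3 tested members, 10 in all, were tested with camera (correlation 0.01, and estimated) and fry. With an estimated correlation camera takes its p-value from the residual degrees of freedom, 2 with all arrays and fewer with 1 left out. Its p-value rose even at a negative estimated correlation, as for dark and sugar starvation and CO2 (correlation -0.46, camera p = 0.056 and 0.19). That version has little power here and does not decide whether correlation between genes accounts for a call. The lists on guard cell function, carbonic anhydrases, nitrogen assimilation, flowering state and vascular tissue had no member to analyse under this annotation. The meristem list had CLV3, below the filter, with signals between 1.4 and 8.6.

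The fits were tested on simulated data made from the fitted means of the 13648 probe sets, with each spread drawn from the trended prior that eBayes fits. With 200 changed probe sets, the CO2 fit recovered 68% of changes of log2 size 1 and 100% of size 2, with 13 false calls. The high minus low fit recovered 37% and 97%, with 11 false calls, and with no change both fits called 0. The simulated noise was normal and independent between probe sets, and the means were exactly additive. Its spread followed the prior that the fit assumes, so the simulation does not show how the fits behave where that prior is wrong. In the real data the CO2 count was 8 with the trend and 0 without it. With fewer changed probe sets the adjusted threshold is stricter, so recovery would be lower. The shares hold only for these settings.

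Alternatives fixed before the data were examined were quantile normalization, equal medians, no filter, the top 40%, a pseudocount of the 25th percentile of signal, eBayes without trend or with a robust prior, other light and CO2 terms, the CO2 group from the atmosphere entry (4 ambient and 2 high), leaving out both high-light arrays, and leaving out each array. Leaving out each array with an estimated correlation in camera was added after the results were seen.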

Results

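The series title asks which genes underlie a change in the number of stomata when carbon dioxide is raised. RNA came from the centre of the rosette, up to leaf 11, of Arabidopsis thaliana Col-0, the standard laboratory accession. Plants grew in compost at 21 degrees C with 10 h of light and 14 h of darkness, at growth stages 3.20 to 3.50. Plants received high, medium or low light in ambient or high CO2, and each of these 6 combinations was measured on 1 ATH1 array, a short-oligonucleotide array with 22810 probe sets. No combination was replicated, so the spread behind each p-value is the departure of the 6 arrays from the fitted model, with 2 residual degrees of freedom per probe set. That model is additive in light and CO2, except in the test of a CO2 difference along the light order. The number of arrays limits the precision. The light intensities and the CO2 concentrations are not given in the sources used here. The labels of the high-light high-CO2 array conflict: its title names high CO2 and its atmosphere entry names normal air. It was placed by its title, and calls that changed with the atmosphere entry are given with the genes concerned. The 6 arrays had the same 2% trimmed mean signal, 100 on each, and median signals between 40.7 and 43.2. Changes are differences of log2 signal with the standard error of the limma fit.

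Light changed more probe sets than CO2 did, 1228 against 8. Across CO2 levels, high minus low light, AT2G20670 fell, with a log2 change of -5.74 ± 0.36 (adjusted p = 0.000508), from signals of 247 and 394.1 in low light to 6.8 and 5 in high light. These high-light signals lie under the filter cutoff of 26.7 and detection calls were not used, so the size of the fall is not firm. The same holds for 8 of the 24 named genes of this comparison, whose signals on the lower side were all under the cutoff: AT2G20670, AT2G05540, PDF1.2, AT5G52760, AT3G13175, AT4G19430, AT4G32800 and AT5G17760. AT5G62210, AT1G07050, AT1G52770, AT1G13650, AT3G19030 and AT5G03230 had 1 of 2 such signals under it. AT2G05540 fell by 5.04 ± 0.23 on the log2 scale (adjusted p = 0.000282) and AT1G49500 changed by -3.88 ± 0.27. LHCB4.3, a light-harvesting antenna protein of photosystem II, rose 5.92-fold (log2 2.57 ± 0.13, adjusted p = 0.000282), from 129.8 and 111.1 in low light to 714.6 and 707.3 in high light. EXPA8, an expansin that loosens cell walls, fell by 2.37 ± 0.18 on the log2 scale, and AT3G21670, a nitrate transporter family gene, by 2.80 ± 0.19. All probe sets past the threshold moved the same way at both CO2 levels. The threshold requires this, since the spread is the departure of the CO2 differences from one another, so it is no separate evidence. In total 1228 of 13648 probe sets changed, 570 higher and 658 lower in high light. Of these, 571 carried 1 gene name and 627 changed at least 2-fold.

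The other named genes that rose with light were PDF1.2, a plant defensin of the jasmonate and ethylene pathway (log2 3.39 ± 0.72, adjusted p = 0.0273), AT5G62210 (3.33 ± 0.47), AT5G52760 (3.04 ± 0.74), AT3G13175 (2.98 ± 0.31), AT4G19430 (2.79 ± 0.32), EXO (2.77 ± 0.69), AT1G07050 (2.74 ± 0.32), AT4G32800 (2.74 ± 0.55), RING1, a RING-finger ubiquitin ligase (2.64 ± 0.20), AT5G17760 (2.53 ± 0.34) and AT1G52770 (2.47 ± 0.24). The named genes that fell were AT1G13650 (-3.60 ± 0.20), AT1G23390 (-3.39 ± 0.32), AT5G19120 (-2.94 ± 0.49), AT3G19030 (-2.82 ± 0.35), AT5G03230 (-2.74 ± 0.62), AT4G38690 (-2.42 ± 0.19) and AT5G48490 (-2.41 ± 0.13). The size of the EXO rise depended on the high-light ambient-CO2 array, with a signal of 1594.5 there and 148.9 in high light with high CO2, and it was 1.15 without that array, where it still passed, and 4.39 without the high-light high-CO2 array. Without the same 2 arrays in turn AT5G03230 was -1.35 and -4.13, PDF1.2 5.03 and 1.76, AT5G52760 1.58 and 4.51, and AT4G32800 1.57 and 3.9. PDF1.2 had 483.9 in high light with high CO2 and 33.8 in high light with ambient CO2. Calls lost with 1 array left out were those of AT5G52760 and AT4G32800 (adjusted p = 0.127 and 0.0522 without the high-light ambient-CO2 array, also lost without either low-light array), EXO (0.25) and AT5G03230 (0.208) without the low-light ambient-CO2 array, and PDF1.2 (0.136), AT5G19120 (0.0707) and AT5G03230 (0.0717) without the low-light high-CO2 array. With the atmosphere entry PDF1.2 (0.115) and EXO (0.175) were lost, and with quantile normalization EXO (0.0665) and AT5G52760 (0.0552).

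**Figure D1:**
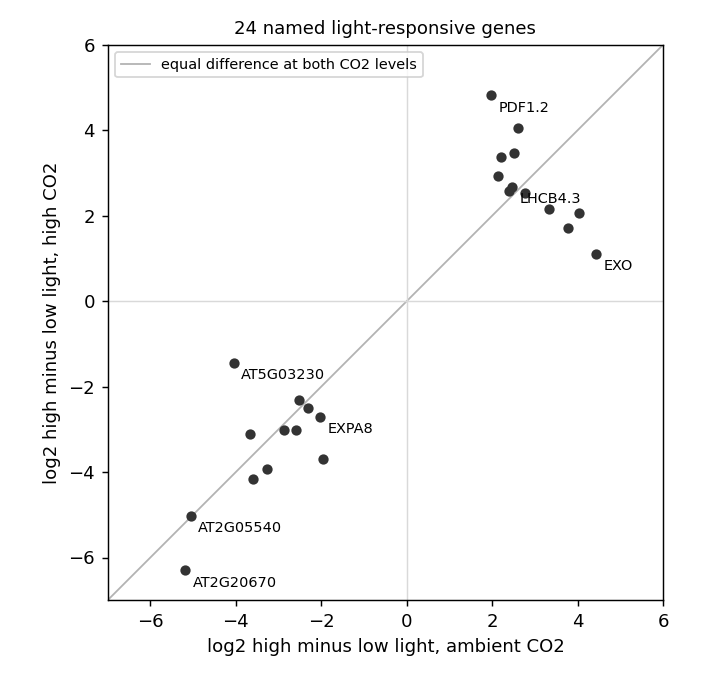
Each point is 1 of the 24 named genes of the high minus low light comparison. The horizontal axis is its log2 difference in ambient CO2 and the vertical axis its log2 difference in high CO2, each from 1 pair of arrays, and the grey line marks equal differences. LHCB4.3 lies close to the line (2.46 and 2.67), and EXO (4.43 and 1.11) and PDF1.2 (1.97 and 4.81) lie far from it.

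Among the gene lists fixed before the data were examined, anthocyanin and flavonoid synthesis rose with light in 3 of 3 tested members. These were DFR, dihydroflavonol reductase (log2 1.48 ± 0.28, adjusted p = 0.02), the flavonoid glucosyltransferase gene UGT78D2 (0.84 ± 0.18, adjusted p = 0.0296) and UF3GT (1.70 ± 0.40, adjusted p = 0.0386). The camera test gave the list adjusted p = 0.017, and adjusted p = 0.67 with an estimated correlation. Here and below, the estimated version rests on at most 2 residual degrees of freedom. A list could hardly pass it, so it does not show that correlation between genes undid a call. The shade avoidance list fell in 2 of 4 members, EXPA8 and IAA29, an auxin-response repressor (log2 -1.40 ± 0.16, adjusted p = 0.00393), while YUC2 (0.01 ± 0.18) and FHL (-0.18 ± 0.32) did not pass. Its camera test gave adjusted p = 0.018, and adjusted p = 0.67 with an estimated correlation. In cell division, the mitotic kinases AUR1 (0.91 ± 0.17, adjusted p = 0.0174) and AUR2 (1.14 ± 0.18, adjusted p = 0.0107) rose and the replication helicase gene MCM7 (0.03 ± 0.14) did not pass, with adjusted p = 0.06 for the list. In light harvesting, LHCB4.1 (-0.21 ± 0.10) and LHCB4.2 (-0.33 ± 0.10) did not pass next to the rise of LHCB4.3, so the list's median (-0.21) and mean (0.68) had opposite signs; its camera test gave adjusted p = 0.95 and its directional fry test adjusted p = 0.04. The directional fry test did not pass for the anthocyanin (0.15), shade avoidance (0.067) or cell division (0.065) lists. The mixed fry test, which ignores direction, gave adjusted p = 0.011 for light harvesting, 0.012 for shade avoidance, 0.024 for cell division, 0.035 for photorespiration, 0.05 for stomatal development and 0.09 for anthocyanin. In starch breakdown, PWD, phosphoglucan water dikinase, rose (0.97 ± 0.18, adjusted p = 0.0169) and DPE1 (0.66 ± 0.18) did not pass. Without the high-light ambient-CO2 array the adjusted p was 0.0568 for DFR, 0.156 for UGT78D2 and 0.182 for UF3GT, with DFR at 0.93 and UF3GT at 0.88 (2.03 and 2.51 without the high-light high-CO2 array), and these 3 calls were also lost without the low-light ambient-CO2 array or with the atmosphere entry, with which DPE1 passed (0.85, adjusted p = 0.0345). UGT78D2 and UF3GT also lost theirs without the low-light high-CO2 array, and UF3GT with quantile normalization (0.0518). Without the low-light high-CO2 array the calls of AUR1 (0.171), AUR2 (0.0725) and PWD (0.113) ended, AUR2 and PWD also without the low-light ambient-CO2 array and AUR1 with the atmosphere entry (0.0522). The shade avoidance list had adjusted p = 0.051 without the high-light high-CO2 array, and cell division passed without the high-light (0.024) or low-light (0.035) ambient-CO2 array, but had adjusted p = 0.58 and 0.87 in these fits with an estimated correlation, and 0.67 with all arrays.

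No member of 4 further lists with at least 3 tested members passed in high minus low light. These were photorespiration (GLYK -0.40 ± 0.14, GDCH2 0.16 ± 0.16, GLDT 0.10 ± 0.12 and PLGG1 0.05 ± 0.11), the Calvin-Benson cycle (PRK -0.28 ± 0.12, SBPASE -0.13 ± 0.12, RCA -0.11 ± 0.11), the abscisic acid, cold and drought list (COR15A 0.61 ± 0.44, COR15B 0.38 ± 0.26, COR47 -0.52 ± 0.38, LTI30 0.11 ± 0.38) and the reference genes (TIP41L 0.35 ± 0.18, SAND 0.13 ± 0.15, GAPC2 -0.09 ± 0.10, UBC21 -0.05 ± 0.14). In the dark and sugar starvation list only EXO passed, with MCCA at -0.61 ± 0.18 and IVD at 0 ± 0.26. Lists with fewer tested members gave WSD1, a wax ester synthase (1.07 ± 0.35), APL3 (1.07 ± 0.31) and SBE2.2 (-0.05 ± 0.16) of starch synthesis, GI of the circadian clock (0.67 ± 0.22), SAG101 (0.48 ± 0.27), ZAT10 (1.71 ± 0.76) and WRKY53 (1.16 ± 0.35), none of which passed over all probe sets. Members below the expression filter were A5GT, an anthocyanin glucosyltransferase gene, with signals of 135.4 and 38.3 in high light and 2.3 and 1.2 in low light, 5MAT with 66.6 and 29.6 against 15 and 13.4, and APL4, THI2.1 and SAG29, whose signals lay between 2.8 and 27. Without the high-light high-CO2 array COR15A was 1.53, COR15B 0.86, LTI30 0.92, GI 1.04, WSD1 1.69, ZAT10 3.48, WRKY53 1.78 and DPE1 0.88. Without the high-light ambient-CO2 array COR47 was -1.39, ZAT10 -0.06, WRKY53 0.53, WSD1 0.46, GI 0.3 and DPE1 0.43. The abscisic acid, cold and drought list passed in opposite directions in these 2 fits, with a median of 0.89 (adjusted p = 0.0042) and -0.50 (0.019), against adjusted p = 0.95 with all arrays, and with an estimated correlation the adjusted p was 0.71 and 0.58. With the atmosphere entry GI passed (1.07, adjusted p = 0.0214). Without either medium-light array GI, WSD1, DPE1 and APL3 passed. The APL3 value ranged from 0.55 to 1.6 with 1 array left out. Adjusted over the list alone, 2 of 2 starch breakdown genes, 2 of 3 light-harvesting genes, 2 of 3 dark and sugar starvation genes and 1 of 2 starch synthesis genes passed. The single tested members WSD1, GI, PDF1.2 and WRKY53 had an unadjusted p under 0.05, since a list of 1 leaves nothing to adjust. The anthocyanin, shade avoidance, cell division and stomatal lists kept counts of 3, 2, 2 and 1 adjusted over the list alone.

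The count for high minus low light was 726 without an intensity trend in the spread, 737 without the expression filter and 806 without a CO2 term. It was 526 without the low-light ambient-CO2 array and 301 without the low-light high-CO2 array, the lowest of the counts with 1 array left out.

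Stomatal development genes are those the series title concerns. SPCH, the transcription factor that starts the stomatal lineage, rose with light between low and high (log2 2.07 ± 0.49, adjusted p = 0.0387) and between low and medium (2.17 ± 0.49, adjusted p = 0.0498). Its signals in low, medium and high light were 32.4, 70.1 and 67.7 in ambient CO2 and 5.6, 52.6 and 47.4 in high CO2. The signal of 5.6 lies under the filter cutoff of 26.7, so the sizes that use it are not firm. SPCH was lower in high CO2 in 3 of 3 light levels, with log2 differences of -2.53, -0.41 and -0.51 at low, medium and high light, but the CO2 comparison did not pass (-1.15 ± 0.40, adjusted p = 0.463). Without the low-light high-CO2 array the high minus low difference of SPCH was 1.04 with adjusted p = 0.125, without the low-light ambient-CO2 array 3.11 and still past the threshold, without the high-light high-CO2 array 1.59 with adjusted p = 0.058, with quantile normalization 2.02 with adjusted p = 0.0531, and with the atmosphere entry 1.34 with adjusted p = 0.192. The medium minus low call of SPCH was also lost with quantile normalization, with the atmosphere entry, and without either medium-light array or the low-light high-CO2 array, and its size ranged from 1.14 to 3.21 with 1 array left out.

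FAMA, which acts late in guard cell formation, had log2 0.47 ± 0.18 for light (adjusted p = 0.161) and -0.09 ± 0.15 for CO2. STOMAGEN, a secreted peptide that promotes stomata, had 0.07 ± 0.14 for light and -0.19 ± 0.11 for CO2. CRSP, a secreted protease linked to CO2 control of stomatal number, had -0.34 ± 0.23 and -0.12 ± 0.19, and AGL16 had 0.01 ± 0.19 and 0.31 ± 0.15, and none of these passed. MUTE, which acts between SPCH and FAMA, lay below the expression filter, with signals of 2.9, 16.2 and 14.8 in low, medium and high light in ambient CO2 and 6.4, 13.7 and 17.2 in high CO2. The list's camera test gave adjusted p = 0.46 for CO2 and 0.62 for light. HIC, SDD1, TMM, EPF1 and EPF2 were not analysed here, since the probe annotation used names no probe set for them.

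**Figure D2:**
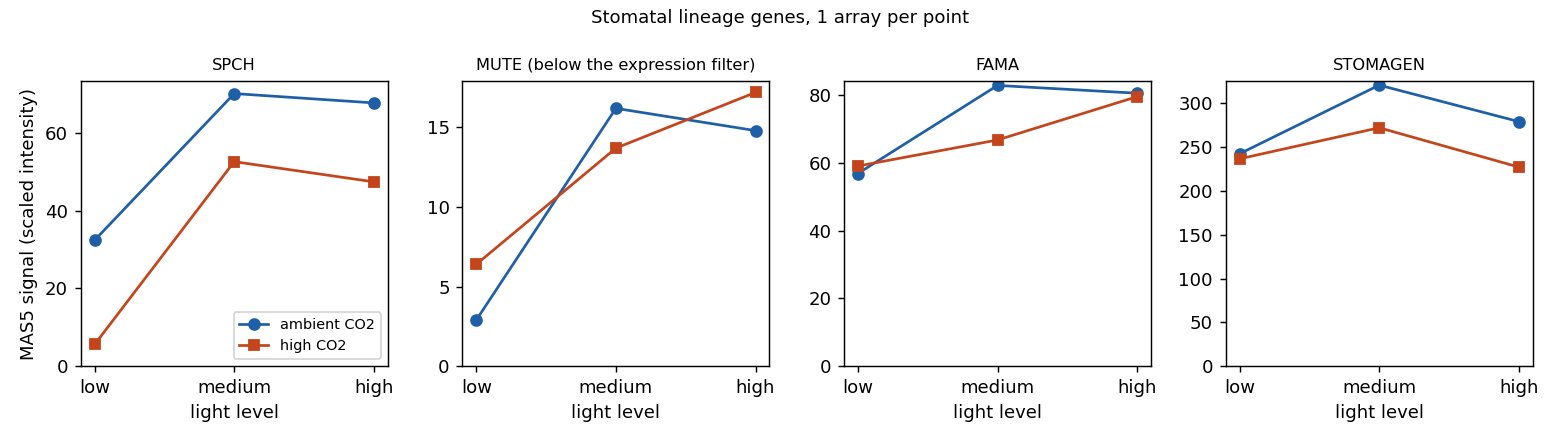
MAS5 signal (vertical axis, scaled intensity) of SPCH, MUTE, FAMA and STOMAGEN at low, medium and high light (horizontal axis) in ambient CO2 (circles) and high CO2 (squares), 1 array per point. SPCH had its lowest signal, 5.6, in low light with high CO2, and its signals in medium and high light lay between 47.4 and 70.1.

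Between ambient and high CO2, 8 probe sets changed, 7 higher and 1 lower in high CO2. Each had the same direction in 3 of 3 light levels. That agreement follows from the threshold, since the spread is the departure of these differences from one another. Of the 8, only AT5G55450, a lipid transfer protein family gene, had a gene name. It was 2.31-fold higher (log2 1.21 ± 0.14, adjusted p = 0.0432), with differences of 1.00, 1.57 and 1.05 at low, medium and high light. The probe annotation used here does not name the others. Of these, 251673_at (2.34 ± 0.18, adjusted p = 0.019) and 262832_s_at (2.24 ± 0.25) rose, with ambient signals under the cutoff of 26.7 at low and medium light (16.9 and 15.2, and 12.7 and 15.7), so these sizes are not firm, and 267256_s_at (-1.27 ± 0.12, adjusted p = 0.024) was the fall. Of the 7 that rose, 5 also rose from low to high light, where independent lists would share 0.292, although both tests use the same spread for each probe set. An unadjusted p under 0.05 was reached by 1178 probe sets, where 682 would be reached by chance.

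The rule filled its places by smallest p from named genes not past the threshold, with an at least 2-fold change and the same sign at each light level. Further genes, EXO among them, met these conditions with a larger p and are not listed. Those taken with higher signal in high CO2 began with AT5G18470 (1.42 ± 0.18, adjusted p = 0.0923), AT5G62360 (1.03 ± 0.15), AT3G23550 (1.13 ± 0.20), AT1G07050 (1.39 ± 0.26), AT4G38550 (1.11 ± 0.21) and AT1G35710 (1.01 ± 0.22). The same group held AT5G25440 (1.25 ± 0.29), AT1G52200 (1.09 ± 0.29), AT1G79470 (1.81 ± 0.52), AT3G03550 (1.09 ± 0.37) and PDF1.2 (1.66 ± 0.59). Those with lower signal were the nitrate transporter family gene AT3G21670 (-1.20 ± 0.16, adjusted p = 0.0923), AT1G13650 (-1.12 ± 0.16), AT1G62660 (-1.12 ± 0.20), AT3G19030 (-1.41 ± 0.29), AT1G47400 (-1.53 ± 0.37), WSD1 (-1.10 ± 0.29), AT5G66650 (-1.49 ± 0.41), AT2G33850 (-1.03 ± 0.33), AT4G24380 (-1.04 ± 0.34), AT2G39650 (-1.42 ± 0.46), SPCH and AT1G72940 (-1.06 ± 0.45). Without the high-light high-CO2 array 11 of these passed, namely AT5G18470 (adjusted p = 0.0167), AT5G62360 (0.00105), AT1G07050, AT4G38550, AT1G35710, AT5G25440, AT1G79470, AT3G21670 (0.00411), AT1G13650, AT1G47400 and AT3G19030 (0.0381). In the same fit AT1G72940 moved to -0.22, AT2G39650 to -0.58, AT4G24380 to -0.43, PDF1.2 to 0.57, AT5G66650 to -0.81, WSD1 to -0.69, AT1G52200 to 0.76, AT1G62660 to -0.88 and AT1G13650 to -0.99. Leaving out an array of another light level brought AT3G03550 to 0.46, AT2G33850 to -0.46, SPCH to -0.46, AT1G35710 to 0.66, AT4G38550 to 0.76, AT5G25440 to 0.85, AT5G62360 to 0.92, AT1G79470 to 0.94 and AT1G47400 to -0.99. For these genes a size of 2-fold therefore depends on 1 light level, and 15 of the 23 genes of this group had at least 1 signal on the lower side under 26.7.

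No member of any gene list passed for CO2 over all probe sets. The anthocyanin list had DFR at -0.79 ± 0.23, UF3GT at -0.74 ± 0.32 and UGT78D2 at -0.27 ± 0.15, all negative at each light level. Its camera test gave adjusted p = 0.019, adjusted p = 0.77 with an estimated correlation and 0.5 in the directional fry test. Without the high-light ambient-CO2 array its median moved from -0.74 to -0.19 with adjusted p = 0.28, and without the high-light high-CO2 array to -0.19 with adjusted p = 0.23. Members close to 0 included the photorespiration genes GDCH2 (-0.25 ± 0.13), GDCH3 (0.10 ± 0.10), PLGG1 (-0.11 ± 0.09) and GLDT (-0.04 ± 0.10), the Calvin-Benson genes RCA (0.16 ± 0.09), SBPASE (-0.03 ± 0.09) and PRK (-0.02 ± 0.10), and LHCB4.1 (0.20 ± 0.08), LHCB4.2 (0.10 ± 0.09) and LHCB4.3 (-0.15 ± 0.11), of which RCA, LHCB4.1 and LHCB4.2 turned negative with quantile normalization. Cell division gave AUR1 -0.24 ± 0.14, AUR2 -0.14 ± 0.15 and MCM7 -0.02 ± 0.12. Shade avoidance gave IAA29 0.31 ± 0.13, YUC2 0.17 ± 0.15, EXPA8 -0.06 ± 0.14 and FHL 0.09 ± 0.26. Starch genes gave PWD 0.44 ± 0.14, DPE1 0.23 ± 0.15, APL3 -0.48 ± 0.26 and SBE2.2 -0.21 ± 0.13.

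The remaining CO2 values were GI 0.54 ± 0.18, ZAT10 -0.96 ± 0.62, WRKY53 -0.11 ± 0.29, SAG101 -0.02 ± 0.22, EXO -1.26 ± 0.56 (-0.17 without either high-light array), MCCA -0.25 ± 0.15 and IVD -0.07 ± 0.21. COR15A had 0.23 ± 0.36, COR15B 0.40 ± 0.21, COR47 0.14 ± 0.31 and LTI30 -0.09 ± 0.31, and the reference genes TIP41L 0.07 ± 0.14, UBC21 0.05 ± 0.11, GAPC2 0.04 ± 0.09 and SAND 0.03 ± 0.12. Adjusted over the list alone, DFR and PWD passed. The single tested members WSD1, GI and PDF1.2 had an unadjusted p under 0.05, since a list of 1 leaves nothing to adjust. With 1 array left out, DFR shrank to -0.43, PWD to 0.25 and GI to 0.27. Without the high-light high-CO2 array COR47 (0.72, adjusted p = 0.0202) and GI (0.79, adjusted p = 0.0302) passed. The abscisic acid, cold and drought list, with adjusted p = 0.54 on all arrays, passed in that fit (median 0.72, adjusted p = 1.3e-06) and without the high-light ambient-CO2 array (1.5e-06), but had adjusted p = 0.73 and 0.74 in these fits with an estimated correlation.

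Some control probe sets moved with CO2. For the CO2 calls above, CO2 and a processing difference between the ambient and high-CO2 samples therefore cannot be told apart. The signal for 25S ribosomal RNA was 840.4, 397.7 and 1723.9 in ambient CO2 at low, medium and high light, and 1627.7, 2286.5 and 2263.6 in high CO2. The actin 3' to 5' ratio, which rises as RNA breaks down, was 5.30, 7.54 and 5.37 in ambient CO2 and 3.99, 5.52 and 4.81 in high CO2. A second pair of actin probe sets gave 2.06, 1.86 and 1.92 against 1.58, 1.80 and 1.60. The GAPDH ratio was 1.21, 1.28 and 1.2 in ambient CO2 against 1.22, 1.26 and 1.22 in high CO2, and a second GAPDH pair gave 1.31, 1.3 and 1.06 against 1.16, 1.13 and 1.06, so the GAPDH ratios did not move at every light level. Some controls also moved from low to high light at both CO2 levels. The 25S signal and the first actin ratio rose, and the second GAPDH ratio fell. The second actin ratio fell in ambient CO2 and rose slightly in high CO2. For the light calls, light and a processing difference between samples of different light levels therefore cannot be told apart either. The CO2 count was 0 without an intensity trend, 0 without the expression filter, 0 without a light term, 0 with light as an ordered score, 0 with the atmosphere entry and 5 with quantile normalization, and AT5G55450 did not pass in these fits (adjusted p = 0.0727 with quantile normalization). It was also lost without the medium-light ambient-CO2 (1.03, adjusted p = 0.0606) or high-CO2 array (1.03, 0.0644), where 5 of the 8 probe sets changed were shared with all arrays. The count was 153 without both high-light arrays, 141 without the high-light ambient-CO2 array, 144 without the high-light high-CO2 array, and 16 without either low-light array.

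**Figure D3:**
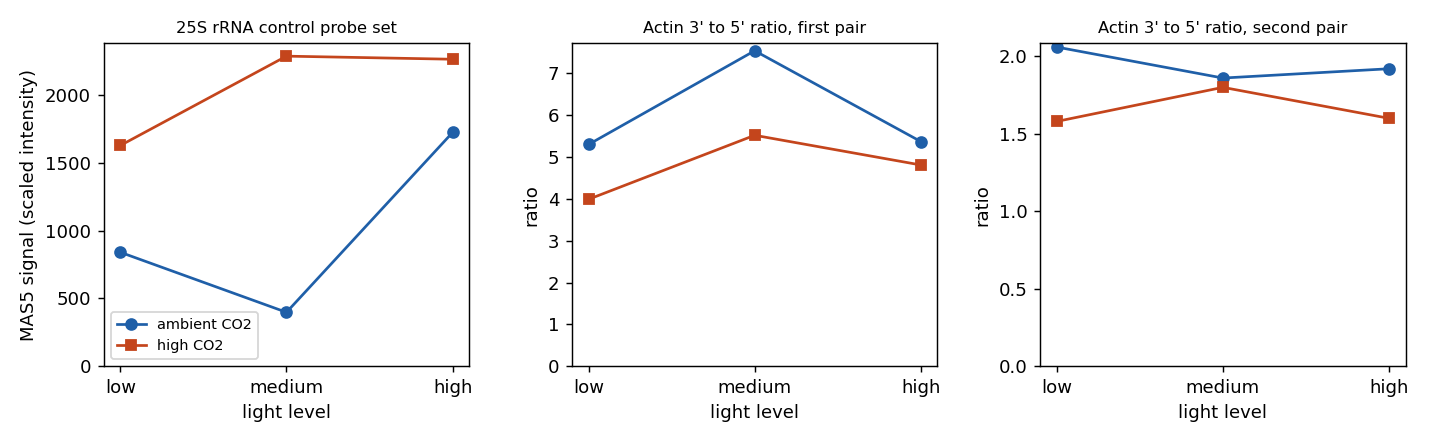
Signal of the 25S ribosomal RNA control (left, scaled intensity) and 3' to 5' signal ratios of 2 actin control pairs (middle and right, no unit) at low, medium and high light (horizontal axis), 1 array per point, in ambient CO2 (circles) and high CO2 (squares). The 25S signal was higher, and both actin ratios lower, in high CO2 at each light level.

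Medium minus low light changed 619 probe sets, 324 higher and 295 lower. AT2G05540 fell by 4.65 ± 0.23 on the log2 scale (adjusted p = 0.000704), AT3G56060 by 2.29 ± 0.22 and AT3G19030 by 2.18 ± 0.35. The medium-light signals of AT2G05540 (17.2 and 13) and AT3G56060 (23.5 and 24.3) and the low-light signals of AT3G13175 (20.5 and 12.4) lie under 26.7, as does 1 low-light signal of AT5G62210 (12), so these sizes are not firm. The named rises were AT5G62210 (2.94 ± 0.47), SPCH and AT3G13175 (2.05 ± 0.31). AUR1 (0.86, adjusted p = 0.0351) and AUR2 (1.05, adjusted p = 0.0272) rose, LHCB4.3 rose (1.84, adjusted p = 0.00335) and EXPA8 fell (-1.13, adjusted p = 0.0213). Without the low-light high-CO2 array AT5G62210 (1.95, adjusted p = 0.0603), AT3G13175 (0.0763), AT3G56060 (0.058) and AT3G19030 (0.0799) did not pass, and all of these but AT3G56060 also failed without the medium-light high-CO2 array. AT3G19030 was also lost without the medium-light ambient-CO2 array (0.0703) and with the atmosphere entry (0.117). With equal medians on all arrays the split was 216 higher and 311 lower. The count was 17 without an intensity trend and 14 without the low-light high-CO2 array, and 1630 without the high-light ambient-CO2 array.

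High minus medium light changed 130 probe sets, 71 higher and 59 lower. With quantile normalization the split was 44 higher and 47 lower. AT1G07050 rose by 2.35 ± 0.32 (adjusted p = 0.0253), AT5G24210 by 2.3 ± 0.37 and RING1 by 1.79 ± 0.20. The named falls were AT2G20670 (-4.17 ± 0.36, adjusted p = 0.011), AT1G13650 (-3.27 ± 0.20) and AT3G21670 (-2.30 ± 0.19). The sizes of AT2G20670, AT1G13650, AT1G07050 and AT5G24210 are not firm, since signals on their lower side were under 26.7. Without the medium-light ambient-CO2 array only AT1G13650 of these 6 passed, with adjusted p = 0.183 for AT1G07050, 0.23 for AT5G24210, 0.114 for RING1 and 0.0545 for AT2G20670 and AT3G21670. AT5G24210 was also lost with quantile normalization (0.0549). The count was 0 without a CO2 term, 1 without an intensity trend, 4 without the medium-light ambient-CO2 array and 852 without the high-light high-CO2 array.

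No probe set passed the limma test for a CO2 difference that changes along the light order, and 226 had an unadjusted p under 0.05, where 682 would be reached by chance. The light score assumes equal steps between light levels. Its spread is the curvature over light, so a light response that is not linear widens it. The lack of calls therefore does not show that the CO2 difference is alike at each light level. Named genes with the smallest p and a change of at least 1 log2 unit per light step were AT1G73930 (1.27 ± 0.30), AT5G05250 (1.23 ± 0.29), AT1G47400 (1.02 ± 0.30), AT3G06070 (-1.01 ± 0.22), AT4G37240 (-1.19 ± 0.28) and EXO (-1.66 ± 0.41), none of which passed. With 1 array left out each of these fell below 1 log2 unit in at least 1 fit, with ranges of 0.62 to 1.92, 0.84 to 1.62, 0.68 to 1.37, -1.36 to -0.66, -1.81 to -0.57 and -2.75 to -0.58 in that order. AT1G73930, AT5G05250 and AT1G47400 had signals under 26.7, so their sizes are not firm. Across probe sets, which are not independent replicates, the CO2 differences at high and medium light had a Pearson correlation of 0.09, those at high and low light 0.16 and those at medium and low light 0.22. High minus low light differences in ambient and in high CO2 had a correlation of 0.61. Without the low-light ambient-CO2 array 30 probe sets passed, among them EXO (-2.75, adjusted p = 0.0464).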

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

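With 1 array per combination, leaving out either array of a light level removes that level's CO2 pair from the CO2 comparison, and the lone array is assumed to vary like the others. No analysis paired by replicate number was possible because every array carries replicate 1. The light factor in the model pairs the CO2 arrays by light level. The cause of the shifts below was not tested, except that fewer arrays or more probe sets tested change a count by construction. The CO2 count of 8 was 5 with quantile normalization or the top 40%, 0 with no filter, without trend, with no light term, with an ordered light score or with the atmosphere entry, and 153 without both high-light arrays, and ranged from 8 to 144 with 1 array left out. High minus low light (1228) gave 737 with no filter, 726 without trend and 806 with no CO2 term, and 301 to 1636 with 1 array left out. Medium minus low light (619) gave 119 with no filter, 17 without trend, 343 with no CO2 term and 368 with the atmosphere entry, and 14 to 1630 with 1 array left out. High minus medium light (130) gave 9 with no filter, 1 without trend, 0 with no CO2 term and 232 with the atmosphere entry, and 4 to 852 with 1 array left out. The count of 0 for CO2 differences along the light order ranged from 0 to 30 with 1 array left out and was 0 in the other fits. Every probe set called in the CO2 or a light comparison kept its direction in each alternative that tested it. This was largely fixed in advance, since the alternatives reuse these arrays and a call needs pairs that agree in sign. The 3 correlations of CO2 differences, 0.09, 0.16 and 0.22, were 0.09, 0.18 and 0.26 with the top 40% and 0.09, 0.16 and 0.22 with quantile normalization, and no spread between replicates exists to judge these shifts.

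Sign changes occurred only in values that had not passed, which largely follows from the threshold. With quantile normalization these were, for CO2, GAPC2 (-0.05), LHCB4.1 (-0.04), LHCB4.2 (-0.06), RCA (-0.05) and the light-harvesting median (-0.06), and for high minus low light IVD (-0.06), YUC2 (-0.05) and the dark and sugar starvation median (-0.06). With the atmosphere entry these were, for CO2, EXPA8 (0.10), GLDT (0.02), LTI30 (0.45), SAG101 (0.11), WRKY53 (0.31) and ZAT10 (0.22), and for light FHL (0.02), GDCH2 (-0.02), IVD (-0.14) and UBC21 (0). With 1 array left out, CO2 differences crossed 0 for COR15A (-0.33 to 0.85), COR47 (-0.19 to 0.72), EXPA8 (-0.24 to 0.10), FAMA (-0.16 to 0.02), FHL (-0.15 to 0.39), GLDT (-0.14 to 0.02), IVD (-0.29 to 0.14), LTI30 (-0.51 to 0.45), MCM7 (-0.07 to 0.03), PRK (-0.12 to 0.08), SAG101 (-0.13 to 0.11), SBPASE (-0.09 to 0.04), UBC21 (-0.03 to 0.10), WRKY53 (-0.43 to 0.31) and ZAT10 (-1.73 to 0.22), and for the medians of the Calvin-Benson (-0.09 to 0.08), abscisic acid (-0.22 to 0.72) and photorespiration (-0.14 to 0.02, with 0.01 without either medium-light array) lists. Light differences crossed 0 for COR15A (-0.32 to 1.53), COR15B (-0.10 to 0.86), COR47 (-1.39 to 0.35), FHL (-0.63 to 0.28), GDCH2 (-0.01 to 0.33), GLDT (-0.06 to 0.26), IVD (-0.33 to 0.33), LTI30 (-0.69 to 0.92), MCM7 (-0.05 to 0.10), SBE2.2 (-0.28 to 0.18), STOMAGEN (-0.04 to 0.19), UBC21 (-0.12 to 0.03), YUC2 (-0.07 to 0.08) and ZAT10 (-0.06 to 3.48), and for the abscisic acid (-0.50 to 0.89), dark and sugar starvation (-0.33 to 0.33), photorespiration (-0.06 to 0.15) and reference gene (0 to 0.09) medians.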

Other observations

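The tests in this part, except the count over other splits of the arrays, were chosen after the results they bear on were seen. The following differences in single pairs of arrays were picked after the values were seen, with no test. At low light, AT1G47400 and AT5G05250 were lower in high CO2, by log2 -2.61 and -2.44 (sizes not firm, since their signals of 13.4 and 13.9 lie under the filter cutoff of 26.7), and BCAT4, a methionine-pathway aminotransferase of glucosinolate synthesis, by -2.50. At medium light, the cold and drought genes COR15A (440.4 against 1123.1) and COR15B (521.3 against 1086.2) had lower signals in ambient than in high CO2, and at high light the opposite held for COR15A (2540.3 against 1271.9, log2 -1), COR15B (-0.24), COR47 (-1.02) and LTI30 (-1.17). At high light, PDF1.2b, a second defensin gene on a probe set of the cross-hybridising class, was higher in high CO2 by 4.34. The 68 tested plastid-encoded probe sets had median CO2 differences of 0.08, 0 and 0.20 at low, medium and high light.

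The conflicting label of the high-light high-CO2 array was examined with probe sets chosen without it. Of the 100 probe sets with the smallest p in the other pairs, 72% moved the same way in the high-light pair, against 43% to 62% for expression-matched random lists, with a median of 0.33 in the chosen direction against 1.18 in the pairs used to choose. The held-out low-light and medium-light pairs each gave 80%, with medians of 0.45 against 1.11 and 0.37 against 1.01, so the held-out median was smaller in every pair. A share above the random range is what growth in high CO2 would give. Both actin ratios and the 25S signal of this pair also differed in the same direction as at the other light levels, so growth in high CO2 and a processing difference between the ambient and high-CO2 samples cannot be told apart.

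In the high-light ambient-CO2 array 30 probe sets were at least 4-fold above every other array, against at most 2 in any other array. Of these 11 carried a gene name, AT3G04640, AT1G72940, AT2G39650, AT3G19680, AT3G57450, AT4G34150, AT4G29780 (792 against at most 84.2), AT4G27280 (2130.9 against 217.4), EXO, CML38, a calmodulin-like gene (227.5 against 33), and STZ, also called ZAT10, a stress-induced zinc finger gene (764.3 against 90.9). AT1G72940 and AT2G39650 are also among the genes listed as lower in high CO2. Noise that scatters alike both ways would put as many below, but 96.8% of the 31 probe sets that far from all others were above (95% interval 83.3% to 99.9%, over probe sets, which are not independent); noise in one direction was not tested. After quantile normalization 29 of the 30 were still 4-fold above. The arrays already had equal trimmed means and close medians, so that step could hardly remove such gaps and does not decide on scaling. A rapid response to handling, or to high light in ambient CO2, may be the source. The probe annotation named only 1 member of the touch and handling list, ZAT10, which is among the 30 and is also on the high light and photoprotection list. This 1 gene cannot separate the sources, and only 1 array shows the pattern, so these stay open.

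At medium light the CO2 difference ran along the light response. Over the 1228 probe sets changed from low to high light, its slope on the light difference was 0.258 (95% bootstrap interval 0.233 to 0.284, over probe sets, which are not independent), and on a scale from low (0) to high light (1) the medium-light arrays lay at 0.42 in ambient and 0.68 in high CO2. The slope was -0.00121 (upper bound 0.032) at low light and 0.00561 (upper bound 0.0378) at high light, so in these arrays it was seen at medium light only. The bounds come from probe sets within 1 pair of arrays per light level and do not measure the spread between samples. They therefore do not decide whether elevated CO2 acts like more light at every level. RNA integrity as read by the actin ratios would give 0.409 at low light and 0.219 at high light, above both bounds, which for the same reason does not decide on it. The log2 25S gap was 2.52 at medium, 0.95 at low and 0.39 at high light, and by it the slopes would be 0.0975 at low light, above the bound, and 0.0402 at high light, close to it, so RNA quality as read by 25S stays open. A difference in light or harvest time between the medium-light samples could produce the slope, as could CO2 at this light level, and with 1 array per combination these cannot be told apart.

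For the CO2 count, the 6 arrays form 10 splits of 3 against 3, too few for a share under 0.05. The real split gave 8 changed probe sets, the highest other 52, and 3 splits gave at least as many, the real one included. The 2 splits with 52 are the same fit, of 1 high-light array against the other, so these counts are not independent. The 3 other splits with 1 array of each light level per group, the form of the real split, each gave 0.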
